A study of Homo sapiens with 12 samples.

How the data were processed

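Nuclei were isolated from 12 pieces of human skin, and their RNA was measured by droplet single-nucleus sequencing of transcript 3' ends. Per the labels' protocols, each of 6 volunteers had 2 nevi of similar place and look chosen, of which 1 was exposed to simulated solar radiation at 3 or 4 times that volunteer's minimal erythema dose (MED, the smallest dose that reddens the skin). Both nevi were taken 24 hours later with a 6 mm punch. A nevus measured at most 5 mm, so each piece held the nevus and a rim of surrounding skin, and it was frozen in embedding medium. The labels do not say which dose each volunteer received, and they mention sequencing lanes without saying which samples shared one, so no batch term could be formed.

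The deposited table holds counts of unique molecular identifiers (UMIs) per gene and nucleus, with no normalization. Per the submitters' processing notes, reads were aligned to GRCh38 and counted with Cell Ranger, whose version is not given, and Seurat 4.1 and 4.3.0 were used in steps the notes do not describe. The values were checked on the file: all were whole numbers of 0 or more, no gene name was repeated, every column belonged to a sample, and the least detected gene had a count in 2 nuclei. The table held 30810 genes and 61773 nuclei. No gene of the mitochondrial genome was in it, so the planned limits of 10 and 2 percent mitochondrial UMIs and the mitochondrial gene list had nothing to act on. Genes of the Y chromosome and of X inactivation, 14 in all, were removed before any test.

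Nuclei with at least 200 genes were kept, which removed none. Doublets were scored per library with Scrublet as built into scanpy 1.11.5. Its automatic threshold called 54 nuclei (0.087 percent), far below the rate usual for such droplets, so the highest scoring nuclei were removed instead, at 0.8 percent of a library per 1000 nuclei: 3471 nuclei, 5.62 percent. The automatic threshold became an added alternative, chosen after the data were seen. Counts of the 58302 nuclei left were scaled to 10000 per nucleus and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1 with a fixed seed, under Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Libraries were not aligned to each other.

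A cluster was named by marker lists of 152 genes fixed beforehand, all present in the table. A marker counted as raised with a log2 fold of at least 1 against all other nuclei (pseudocount 5 CPM, counts scaled to a fixed library total) and a UMI in at least 5 percent of nuclei. A class needed at least 3 raised markers, 40 percent of its list, and a mean log2 fold of 0.5. This named 31 of 35 clusters. The other 4, holding 3046 nuclei, stayed unnamed, and 1 cluster of dividing keratinocytes was kept within keratinocytes but in neither layer. The keratinocyte class joins basal, suprabasal and dividing nuclei. Melanocytes of the epidermis and nevus cells share their markers and form 1 melanocytic class.

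Counts were summed per library and class, and a library entered a class with at least 20 nuclei, in complete pairs only. A class needed 3 pairs. The smallest summed library held 110001 UMIs (mast cells) and the largest class library 29100095 (melanocytic cells). Schwann cells, adipocytes and hair follicle or sebaceous cells were not tested for genes, having too few nuclei, and no B or plasma cell class was found. In 4 of the tested classes 1 pair was too small and 5 pairs were left. The volunteer number pairs the samples and entered every gene test as a block, since both nevi of a pair come from the same volunteer. In a check of the numbers, deviations from the group means correlated at 0.363 on average within a number (from -0.0909 to 0.603) and at -0.0708 between numbers, over 23910 genes, and 4 of 6 control libraries lay closest to their own number. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3), with Benjamini-Hochberg adjustment at 0.05 over the genes of a class. A difference of response between keratinocytes and melanocytic cells was tested as an interaction in 1 edgeR model over both classes. DESeq2 1.42.0 was the second tool.

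Gene lists, 47 in all with 32 besides the cell type markers, were fixed before the data were examined, as were the grouping, the tests and the alternatives of the processing except those named as added. Lists with at least 5 measured genes were tested against the other genes with limma 3.58.1 camera at the preset inter-gene correlation of 0.01, adjusted over the lists of a class, and again with the correlation estimated from the data. Limma fry asked whether a list's genes moved together. Measured genes were too few in every class for 2 lists. Over 13 class tests, 468 list tests were run. Counts of list members passing are given as adjusted over the list alone and over all genes tested. Counts of pairs in which a gene was higher used TMM-scaled CPM. The median change of list genes per pair used log2 of CPM plus 1. Class shares (a count of 0.5 added, logit scale) and measures per library were compared by an exact two-sided sign-flip test over all 64 sign assignments of 6 pairs. Its smallest possible p is 0.03125, and with 5 pairs 0.0625.

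Genes were named by a rule: in keratinocytes, melanocytic cells and all nuclei together the 12 higher and 12 lower genes with the smallest p among those passing and moving the same way in at least 5 of 6 pairs, in other classes 5 and 5, up to 4 members of a list described with the smallest p in that class, cell type markers, CDKN1A and MDM2. Where fewer than 3 genes pass, the 5 with the smallest p are named and said not to pass, which applied to every class. Gene models named only by a clone were passed over, 9 in all over the classes. A few genes that the rule would name are withheld and left out of the text. The notes do not say whether strand was used in counting, so antisense RNAs cannot be told from their partners, and reads of near-identical copies such as KRT6A and KRT6C may be split between them. Positions come from GENCODE release 29 on GRCh38, joined by symbol, which found 28610 of the genes (92.9 percent).

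The tests were also run on simulated data with the fitted spread of 4 classes and known changes. Of 50 genes changed 4-fold per class, edgeR called 70 percent in keratinocytes, 92 percent in melanocytic cells and in blood endothelium and 88 percent in pericytes, and of those changed 2-fold 24, 46, 46 and 20 percent. A list of 25 genes changed 1.5-fold was called by camera in each of the 4 classes with either correlation, and 0 of 40 unchanged lists were. The simulated genes varied independently, unlike real lists such as ribosomal proteins (estimated correlation up to 0.967). The simulation therefore cannot show how either list test behaves when the genes of a list move together.

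Other settings fixed beforehand were DESeq2, no filter on low counts, no volunteer block, doublets kept, counts thinned to the smallest library, Leiden resolutions of 0.5 and 2, minimums of 10 and 50 nuclei, nuclei with at least 500 genes, scaling by relative log expression, the estimated correlation, a centred log-ratio or named classes alone for shares, and leaving out each pair in turn. Added after the data were seen were the automatic doublet threshold, leaving out the melanocytic cluster that 1 library fills, and testing only genes with at least 25 percent of their level over all nuclei, a guard against free RNA. Figures were drawn with matplotlib 3.10.9.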

Results

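RNA was counted in nuclei from 12 pieces of human skin, each holding a nevus (a benign growth of melanocytes) and the skin around it. Of the 2 nevi of each of 6 volunteers, 1 had been exposed 24 hours earlier to simulated solar radiation at 3 or 4 times the smallest dose that reddened that volunteer's skin, and the other was the control. The comparison asks what a burning dose changes in nevus cells and in the surrounding skin cells after a day. Each volunteer's control and irradiated library formed a pair, giving 6 libraries per group. The libraries totalled 5727130 to 68400007 UMIs. Control libraries held 3415 ± 1477 nuclei (SD, n = 6) and irradiated ones 6881 ± 3714, more in 5 of 6 pairs (exact two-sided sign-flip p = 0.156, adjusted over 4 measures 0.438). The median nucleus held 5360.5 ± 1440 UMIs in control and 5265 ± 537 in irradiated libraries (higher in 3 of 6 pairs, exact p = 0.906), and its number of genes was likewise similar (exact p = 0.844). Nuclei ranged from 550 to 220658 UMIs.

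Keratinocytes made up 21.8% ± 8.87 of control nuclei (SD, n = 6) and 17.9% ± 6.59 of irradiated nuclei. Melanocytic cells made up 18.9% ± 15.4 and 18.7% ± 15.9, fibroblasts 15.3% ± 6.11 and 15.1% ± 5.44, and sweat gland cells 5.56% ± 4.12 and 11.7% ± 10.4. The smallest p among 15 class shares belonged to blood endothelium, at 12.3% ± 4.36 in control and 8.88% ± 0.900 in irradiated libraries, lower in 5 of 6 pairs (exact p = 0.0625, adjusted 0.703). Suprabasal keratinocytes stood at 12.01% ± 5.22 and 7.44% ± 3.89 (lower in 5 of 6 pairs, exact p = 0.0938, adjusted 0.703). No share passed. Within classes, clusters differed in makeup, which was looked at only after the clusters were seen and was not tested. Among basal keratinocytes, the cluster led by KRT6A, AREG and KRT16 (cluster 6) held 1.99% ± 4.55 of control and 6.91% ± 5.89 of irradiated nuclei, higher in 5 of 6 pairs. The cluster led by COL17A1 and COL7A1 (cluster 9) held 6.84% ± 5.87 and 2.55% ± 1.88, higher in 1 of 6. Among fibroblasts, cluster 7, led by GREM1 and THBS1 among others, held 1.43% ± 2.38 and 5.22% ± 4.71. Cluster 20, led by COL1A1 and DCN, held 4.44% ± 3.09 and 1.21% ± 1.91 and was lower in 6 of 6 pairs. The myeloid cluster with CD207, the Langerhans cell marker (cluster 29), held 1.09% ± 0.432 and 0.564% ± 0.243, also lower in 6 of 6 pairs. Clusters 6, 7 and 20 were shallow, with medians of 2193, 2187.5 and 2142 UMIs per nucleus against 5068.1, 5077.8 and 4876.5 for their libraries. The library giving the most nuclei held 33.1%, 36.9% and 31.7% of them.

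**Figure D1:**
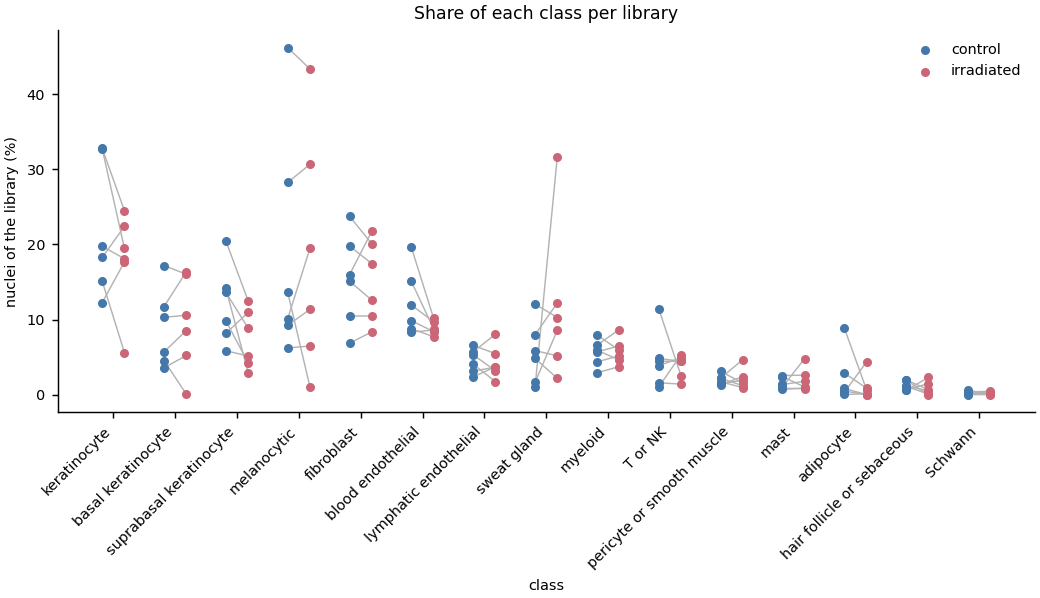
Share of each cell class in each library, in percent of the library's nuclei (vertical axis), by class (horizontal axis). Points are the 12 libraries, blue for control and red for irradiated, and a line joins the 2 libraries of a pair; blood endothelium is lower after irradiation in 5 of 6 pairs.

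Over all nuclei together, camera with the preset correlation called the wound and stress list of keratinocytes, the S phase list and the heat shock and unfolded protein list higher after irradiation. None held with an estimated correlation (adjusted p = 0.484, adjusted p = 0.425 and adjusted p = 0.425). AREG, an epidermal growth factor receptor ligand, was higher by 2.71 ± 0.43 (log2, SE, n = 6 pairs). S100A9, an inflammatory calcium-binding protein, was higher by 4.28 ± 0.92 and KRT16, a keratin of wounded epidermis, by 2.80 ± 0.67, each like AREG in 6 of 6 pairs. In the wound list 11 of 17 genes passed adjusted over the list alone and 0 over all genes tested (limma camera adjusted p = 6.06e-10 with the preset correlation; adjusted p = 0.484 with an estimated correlation). The S phase list was called too (camera adjusted p = 4.13e-10; adjusted p = 0.425 with an estimated correlation). In it 9 of 25 genes passed adjusted over the list alone, among them UHRF1 (1.14 ± 0.27) and MCM6 (0.51 ± 0.12). HSPE1 (0.62 ± 0.10) and HSP90B1 (0.73 ± 0.17), which fold proteins in mitochondria and in the endoplasmic reticulum, were among the leading genes of the heat shock list (camera adjusted p = 1e-07; adjusted p = 0.425 with an estimated correlation). Markers of sweat gland were called higher (median 0.58, higher in 3 of 6 pairs; camera adjusted p = 0.0145; adjusted p = 0.680 with an estimated correlation). That call ended without pair 1 (0.136), 2 (0.233) or 4 (0.0728). Markers of blood endothelium were called lower (median -0.18; camera adjusted p = 0.0343; adjusted p = 0.680 with an estimated correlation), a call that ended without pair 1, 2 or 3, without the volunteer block and without the cluster that 1 library fills (camera adjusted p from 0.0714 to 0.526). Of single genes, edgeR called 0 of 23719, with 2082 at an unadjusted p under 0.05. DESeq2 called 175 higher and 141 lower. Among the genes with the smallest p, which did not pass in edgeR (adjusted p = 0.453 each), were PLEKHH2 (-0.73 ± 0.09; chromosome 2, 43637273 to 43767987 on GRCh38), PKD1L1 (-0.87 ± 0.12), AFF3 (-0.55 ± 0.08) and TSPAN7 (-0.72 ± 0.10). Each had the same sign in 6 of 6 pairs. CDKN1A, the p53 target that arrests the cell cycle, was higher by 1.005 ± 0.37 in 6 of 6 pairs and did not pass either (edgeR adjusted p = 0.530). The list of p53 targets was called higher, 23 of 30 (median 0.19; camera adjusted p = 0.0226; adjusted p = 0.680 with an estimated correlation). That call ended without pair 3 or 6. Camera called this list higher in 3 of 13 class tests. With an estimated correlation 0 of these calls remained, and all 3 ended in at least 1 other setting.

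In keratinocytes camera with the preset correlation called the lists of S phase and wounding higher and the suprabasal markers lower. With an estimated correlation none was called (adjusted p = 0.603, adjusted p = 0.792 and adjusted p = 0.603), and 9 of 25, 9 of 17 and 1 of 10 genes passed adjusted over the list alone, 0 over all genes tested. UHRF1, which keeps DNA methylation through replication, was higher by 1.55 ± 0.29 (log2, SE, n = 6 pairs) and DTL, which limits the licensing of replication, by 1.03 ± 0.19, both in 6 of 6 pairs. All 25 measured S phase genes had a positive change, with a median of 0.68. KRT6A, a keratin of wounded epidermis, was higher by 2.31 ± 0.62 in 5 of 6 pairs, AREG by 3.20 ± 0.69 in 6 of 6, and the median of the wound list was 2.31. All 10 suprabasal markers were lower, KRT10 at -1.19 ± 0.45 and KRTDAP at -0.70 ± 0.19, with a median of -0.76. HSPA5, the chief chaperone of the endoplasmic reticulum, was higher by 1.18 ± 0.22 in 6 of 6 pairs.

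Limma camera with the preset correlation called the S phase list in keratinocytes at an adjusted p = 1.79e-12 (adjusted p = 0.603 with an estimated correlation). Of its genes 9 passed adjusted over the list alone and 0 over all genes tested. For the wound list camera gave 9.15e-05 (adjusted p = 0.792 with an estimated correlation), with 9 of 17 passing adjusted over the list alone. For the suprabasal markers camera gave 0.0011 (adjusted p = 0.603 with an estimated correlation), with 1 passing adjusted over the list alone. The heat shock list was called at 0.0156 by camera (adjusted p = 0.772 with an estimated correlation), with 4 of 22 passing adjusted over the list alone. Markers of another class, the melanocytic one, were called lower in keratinocytes, all 12 of them (median -0.41; camera adjusted p = 0.036; adjusted p = 0.849 with an estimated correlation). That call ended without pair 2, 4 or 5, without the volunteer block, with doublets kept, with automatic doublet calls and at Leiden resolution 2 (camera adjusted p from 0.0565 to 0.885). Of 16002 genes edgeR called 0, with 2502 at an unadjusted p under 0.05, and DESeq2 called 284 higher and 259 lower. Without pair 1 edgeR called 23. The 5 genes with the smallest p did not pass (edgeR adjusted p = 0.192 each). They were MT2A, a metal-binding stress protein (1.56 ± 0.20, from 21.5 ± 11.6 to 66.3 ± 40.8 CPM, SD; chromosome 16, 56608199 to 56609497), PNPLA7 (-0.99 ± 0.14) and the lipoprotein receptor LRP8 (2.04 ± 0.31). The others were the small nucleolar RNA hosts SNHG15 (1.53 ± 0.23) and SNHG8 (0.91 ± 0.14), and all 5 had the same sign in 6 of 6 pairs. CDKN1A was higher by 1.26 ± 0.52 in 5 of 6 pairs and MDM2, the p53 feedback regulator, by 0.53 ± 0.33 in 4 of 6, neither passing (edgeR adjusted p = 0.297 and 0.467). Among the antigen presentation genes of class I, which camera did not call as a list (adjusted p = 0.0588), PSMB9, a subunit of the immunoproteasome, was lower at -1.03 ± 0.25 in 6 of 6 pairs. In that list 4 lower and 2 higher genes passed adjusted over the list alone. The leading keratinocyte cluster was cluster 4, suprabasal, in control and cluster 6, basal, in irradiated libraries, so the class differed in makeup.

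In basal keratinocytes alone (5 pairs), KRT6A was higher by 5.86 ± 1.37 in 4 of 5 pairs, and CDKN1A by 3.24 ± 0.96 in 4 of 5. TIMP1, an inhibitor of matrix proteases, was higher by 2.14 ± 0.35 in 5 of 5. ADAMTS9-AS2, an antisense RNA, was lower at -2.59 ± 0.44 in 5 of 5. The wound list was called (camera adjusted p = 0.000111; adjusted p = 0.751 with an estimated correlation), with 10 of 16 genes passing adjusted over the list alone and 0 over all genes tested. Camera also called the S phase list (1.76e-06; adjusted p = 0.751 with an estimated correlation) and the ribosomal protein list (5.15e-09; adjusted p = 0.617 with an estimated correlation). Melanocytic markers were called lower there too, all 11 measured (median -0.65; camera adjusted p = 0.00726; adjusted p = 0.751 with an estimated correlation), a call that ended without pair 4 or 5, without the volunteer block and with doublets kept (camera adjusted p from 0.0780 to 0.300). In irradiated basal keratinocytes these markers stood at a median of 12.9% of their level over all nuclei, so free RNA could account for it. Of 13632 genes edgeR called 0, with 2671 at an unadjusted p under 0.05, and DESeq2 called 412 higher and 260 lower. Without pair 1 edgeR called 2890. The smallest p belonged to MT2A (1.78 ± 0.24), MYO3A (-2.09 ± 0.32), ERG (1.66 ± 0.27), TIMP1 and ADAMTS9-AS2, which did not pass (edgeR adjusted p = 0.193 each). The change of ERG matches the highest among the markers of blood endothelium measured there (1.66). In irradiated basal keratinocytes those markers stood at a median of 10.8% of their level over all nuclei. Free RNA could therefore account for ERG as well, which was not tested. Cluster 9 led this class in control and cluster 6 in irradiated libraries. In suprabasal keratinocytes (6 pairs), KRT6C was higher by 2.38 ± 0.55 and S100A7 by 3.32 ± 0.80. The wound list was called (camera adjusted p = 6.11e-05; adjusted p = 0.691 with an estimated correlation), with 3 genes passing adjusted over the list alone and 0 over all genes tested. The class I antigen presentation list was called lower there, 13 of 16 (median -0.48; camera adjusted p = 0.00596; adjusted p = 0.691 with an estimated correlation). So were the class's own suprabasal markers, 10 of 10 (median -0.50; camera adjusted p = 0.0131; adjusted p = 0.691 with an estimated correlation). Both calls ended without pair 2 (camera adjusted p = 0.0699 and 0.132) and with thinned counts (0.0722 for both). The class I call also ended with doublets kept (0.0878) and with automatic doublet calls (0.110), and that of the markers without the volunteer block (0.0973) and at Leiden resolution 2 (0.921). There edgeR called 0 of 13200 genes, with 934 at an unadjusted p under 0.05, and DESeq2 called 18 higher and 5 lower. TNC (1.22 ± 0.18; chromosome 9, 115019578 to 115118257), SLC1A3 (1.14 ± 0.19), PNPLA7 (-0.72 ± 0.13), PYGL (0.91 ± 0.17) and THBS1 (1.81 ± 0.35) had the smallest p and did not pass (edgeR adjusted p = 0.697 each).

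In melanocytic cells, which join nevus cells and melanocytes of the epidermis, camera with the preset correlation called the interferon list and the heat shock and unfolded protein list higher. With an estimated correlation neither was called (adjusted p = 0.704 each), both calls ended with thinned counts, and 0 of 25 and 7 of 20 genes passed adjusted over the list alone, 0 over all genes tested. IFITM3, which blocks virus entry, was higher by 1.51 ± 0.42 (log2, SE, n = 6 pairs) and IFI6 by 1.34 ± 0.42, both in 6 of 6 pairs. For IFITM3 the size was uneven. With 5 CPM added and no TMM scaling, it changed by 2.54 and 1.77 in pairs 5 and 6 and by 0.22 to 0.44 in the others. All 25 measured interferon genes had a positive change with a median of 0.56, and the median of the list was higher in 5 of 6 pairs. HSP90B1 was higher by 0.92 ± 0.22 in 5 of 6 pairs, HSPD1 by 0.40 ± 0.11 in 6 of 6 and ATF4, the stress transcription factor, by 0.47 ± 0.13 in 5 of 6. Of the immediate early genes, NR4A3 was higher by 0.93 ± 0.33 and FOS by 1.01 ± 0.43, neither passing adjusted over the list alone. The p53 target CDKN1A stood at 0.62 ± 0.40 in 5 of 6 pairs and MDM2 at 0.07 ± 0.37 in 3 of 6, and neither passed.

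Camera called the interferon list in melanocytic cells at an adjusted p = 1.19e-07 (adjusted p = 0.704 with an estimated correlation), with 0 genes passing adjusted over the list alone. It called the heat shock list at 1.03e-06 (adjusted p = 0.704 with an estimated correlation), with 7 of 20 passing adjusted over the list alone and 0 over all genes tested. Both calls ended when the libraries were thinned to the smallest (camera adjusted p = 0.105 and 0.0549). The immediate early list was called at 0.00113 by camera (adjusted p = 0.704 with an estimated correlation), with 0 genes passing adjusted over the list alone. Markers of basal keratinocytes were called lower in this class, 8 of 10 (median -0.69; camera adjusted p = 0.0303; adjusted p = 0.704 with an estimated correlation). That call ended without pair 4 or 6, without the volunteer block, with doublets kept and with automatic doublet calls (camera adjusted p from 0.0905 to 0.853). In irradiated melanocytic cells these markers stood at a median of 22.7% of their level over all nuclei, so free RNA could account for it. Those of suprabasal keratinocytes, 7 of 7 lower (median -0.79), were not called (camera adjusted p = 0.0710). Of 15001 genes edgeR called 0, with 1129 at an unadjusted p under 0.05, and DESeq2 called 13 higher and 50 lower. The smallest p belonged to OBI1-AS1 (-1.02 ± 0.12, from 71.5 ± 37.7 to 34.9 ± 17.3 CPM, SD; no position in the annotation) and KAZN-AS1 (-1.55 ± 0.21; chromosome 1, 14348955 to 14391575), both antisense RNAs. S100A8 (3.78 ± 0.54), LINC02477 (-2.14 ± 0.33) and FST, a binder of activin (2.79 ± 0.45), followed. All 5 had the same sign in 6 of 6 pairs and none passed (edgeR adjusted p from 0.106 to 0.273). S100A8 stood at 25.4% of its level over all nuclei in irradiated melanocytic cells. Among pigmentation genes MC1R, the melanocortin receptor, stood at -0.52 ± 0.18 and DCT at -0.41 ± 0.18, each higher in 1 of 6 pairs. The pigmentation list was called lower, 20 of 26 (median -0.16, camera adjusted p = 0.0303, and adjusted p = 0.704 with an estimated correlation), with 0 genes passing adjusted over the list alone. This call ended without pair 2 (camera adjusted p = 0.117), 4 (0.175) or 6 (0.297), without the cluster that 1 library fills (0.357), with automatic doublet calls (0.0899), with thinned counts (0.0645) and with a minimum of 50 nuclei (0.117). With nuclei pooled over libraries, cluster 1 led the class in control and cluster 3, of which 97.3% came from 1 library, in irradiated libraries. By the mean share per irradiated library cluster 1 was not behind (6.87% ± 10.3 against 6.18% ± 14.2, SD).

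**Figure D2:**
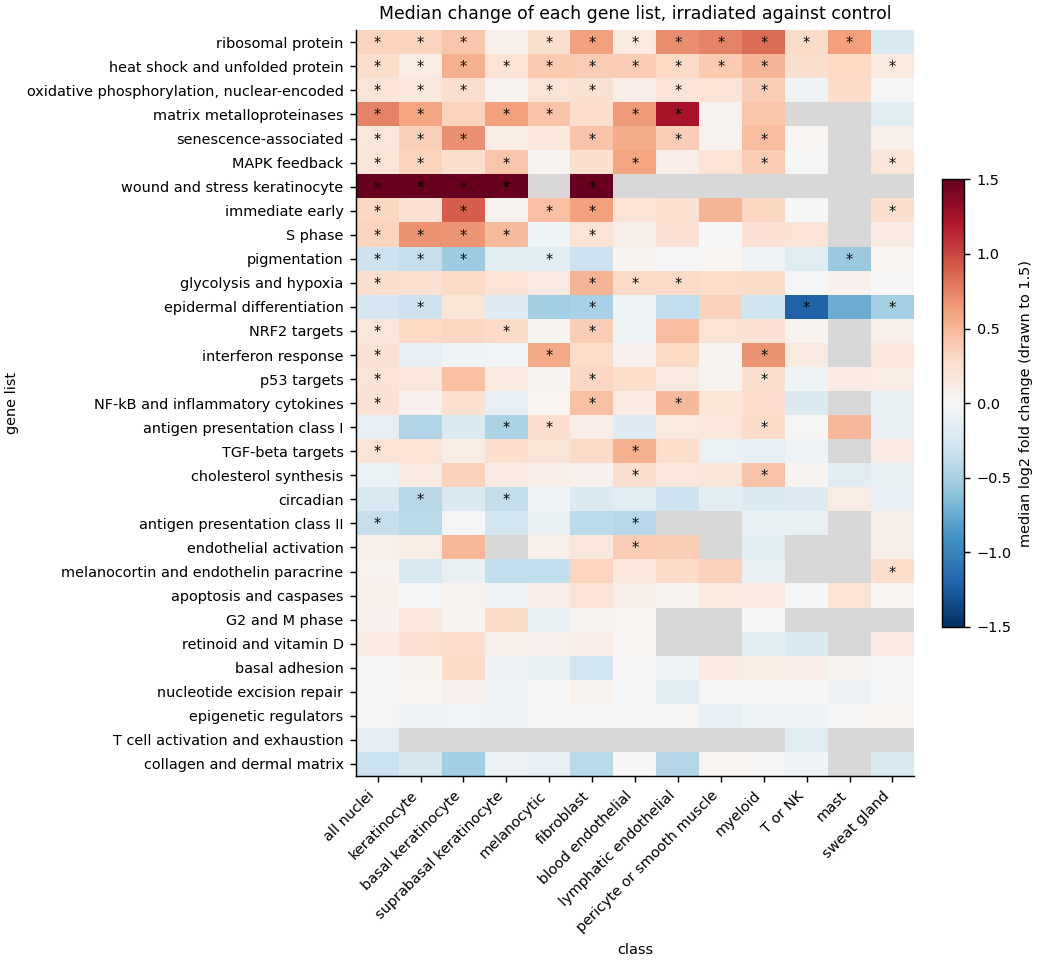
Median log2 fold change, irradiated against control, of each gene list (vertical axis) in each class (horizontal axis). Colour gives the median, drawn to 1.5 in either direction, grey marks lists with fewer than 5 measured genes, and a star marks a camera call at the preset correlation, none of which held with an estimated correlation. The heat shock list is higher in each of the 13 columns, which overlap, as all nuclei hold every class and keratinocytes both layers.

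In fibroblasts camera with the preset correlation called the glycolysis and heat shock lists higher. Neither was called with an estimated correlation (adjusted p = 0.542 each), and 6 of 24 and 4 of 19 genes passed adjusted over the list alone, 0 over all genes tested. CDKN1A, which did not pass (edgeR adjusted p = 0.187), was higher by 1.86 ± 0.49 (log2, SE, n = 6 pairs), LDHA, the enzyme making lactate, by 1.16 ± 0.26 and HSPA5 by 0.91 ± 0.22, each in 6 of 6 pairs. ENO1, a glycolytic enzyme, was higher by 0.95 ± 0.21 in 5 of 6. DHRS3, which reduces retinal, was higher by 1.44 ± 0.18 and HGF, a growth factor for melanocytes, by 1.52 ± 0.37, while ASIP, the melanocortin antagonist, was lower at -0.88 ± 0.21, all in 6 of 6 pairs. HLF (-1.17 ± 0.30) and TEF (-0.91 ± 0.25), clock-controlled transcription factors, were lower in 6 of 6 pairs.

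Camera called the fibroblast glycolysis list at an adjusted p = 0.000813 (adjusted p = 0.542 with an estimated correlation), with 6 of 24 genes passing adjusted over the list alone and 0 over all genes tested. It called the heat shock list at 0.000152 (adjusted p = 0.542 with an estimated correlation), with 4 of 19 passing adjusted over the list alone. Markers of other classes moved in fibroblasts as well. Those of suprabasal keratinocytes were called lower, 6 of 6 (median -0.56; camera adjusted p = 0.0150; adjusted p = 0.636 with an estimated correlation), as were those of blood endothelium, 10 of 10 (median -0.44; camera adjusted p = 0.0401; adjusted p = 0.636 with an estimated correlation). Those of sweat gland were called higher, 7 of 7 (median 0.46; camera adjusted p = 0.0294; adjusted p = 0.563 with an estimated correlation). The first of these calls ended without pair 4, without the volunteer block and with automatic doublet calls (camera adjusted p from 0.115 to 0.671). The second ended without pair 2, 4 or 6, with doublets kept and with automatic doublet calls (0.0612 to 0.755), and the third without pair 1 or 2 and without the volunteer block (0.0827 to 0.257). In irradiated fibroblasts these markers stood at medians of 13.9%, 19.5% and 18.6% of their level over all nuclei. Free RNA from other cells could therefore account for these calls, which was not tested. The NF-kB list was called at 0.00699 (camera; adjusted p = 0.636 with an estimated correlation), with SOD2 at 0.97 ± 0.32. The p53 target list was called higher, 23 of 28 (median 0.31; camera adjusted p = 0.0138; adjusted p = 0.636 with an estimated correlation). It was no longer called without pair 3 or 6 or with thinned counts. The circadian list was not called (camera adjusted p = 0.147), yet 5 of its genes were higher and 5 lower adjusted over the list alone. The wound list, of which 5 genes were measured, was called at 0.0065 (camera; adjusted p = 0.542 with an estimated correlation), and its leading gene KRT16 (2.78 ± 0.63) stood at 17.0% of its level over all nuclei. Of 15388 genes edgeR called 0, with 2534 at an unadjusted p under 0.05, and DESeq2 called 209 higher and 330 lower. IL1RAPL1 (-1.47 ± 0.17, from 286 ± 129 to 107 ± 56.8 CPM, SD; chromosome X, 28587399 to 29956723), DPY19L2 (-1.59 ± 0.19), DHRS3, MARCH3 (1.88 ± 0.26) and RHOJ (-0.93 ± 0.13) had the smallest p. Each had the same sign in 6 of 6 pairs, and none passed (edgeR adjusted p = 0.0752 each). Without pair 1 edgeR called 2 genes (MARCH3 and AP000331.1), without pair 2 it called 3 (CCR3, MROH9 and TRHDE) and without pair 4 it called 1 (LHFPL3). All but MARCH3 were named only after their values were seen. With nuclei pooled over libraries, cluster 2 led the class in control and cluster 7 in irradiated libraries. By the mean share per irradiated library cluster 2 was not behind (5.37% ± 2.15 against 5.22% ± 4.71, SD), so the change of leader depends on the larger libraries.

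In blood endothelial cells camera with the preset correlation called the lists of MAPK feedback and TGF-beta targets higher. With an estimated correlation neither was called (adjusted p = 0.447 and adjusted p = 0.483), and 5 of 14 and 3 of 15 genes passed adjusted over the list alone, 0 over all genes tested. COL4A1, a chain of basement membrane collagen, was higher by 1.92 ± 0.28 (log2, SE, n = 6 pairs; from 235 ± 328 to 600.5 ± 308 CPM, SD; chromosome 13, 110148963 to 110307233) and COL4A2 by 1.59 ± 0.25, both in 6 of 6 pairs. SMAD6 (1.65 ± 0.32) and SMAD7 (1.10 ± 0.28), inhibitors within the TGF-beta pathway, and SPRY4 (1.68 ± 0.38), a brake on growth factor signals, were higher in 6 of 6 pairs. So were HSPA5 (1.41 ± 0.30) and KDR, a receptor of vascular growth factor (0.60 ± 0.11). TENM2 was lower at -1.48 ± 0.22 in 6 of 6.

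Camera called the MAPK feedback list in blood endothelium at an adjusted p = 0.000176 (adjusted p = 0.447 with an estimated correlation), with 5 of 14 genes passing adjusted over the list alone and 0 over all genes tested. The TGF-beta list followed at 0.0031 (camera; adjusted p = 0.483 with an estimated correlation), with 3 of 15 passing adjusted over the list alone. The heat shock list was called at 0.000121 (camera; adjusted p = 0.483 with an estimated correlation), with 2 of 17. Of 13292 genes edgeR called 0, with 1815 at an unadjusted p under 0.05, and DESeq2 called 134 higher and 127 lower. The other genes with the smallest p were PLPP3 (1.52 ± 0.23) and IQCJ-SCHIP1 (1.23 ± 0.19), and none of the 5 passed (edgeR adjusted p = 0.140 each). Without pair 1 edgeR called 33 genes and without pair 2 it called 208. In lymphatic endothelium (6 pairs), IGFBP5, which binds insulin-like growth factors (chromosome 2, 216672105 to 216695525), was higher by 2.29 ± 0.29 in 6 of 6 pairs and NAMPT by 1.48 ± 0.27. NCALD (-0.87 ± 0.14), C12orf42 (-2.41 ± 0.41) and LDLRAD4 (-0.86 ± 0.16) were lower, and none of the 5 passed (edgeR adjusted p from 0.0642 to 0.192). There edgeR called 0 of 9695 genes, with 920 at an unadjusted p under 0.05, and DESeq2 called 31 higher and 55 lower. Without pair 1 edgeR called 1 (STEAP1B) and without pair 2 it called 3 (IGFBP5, C12orf42 and CR381670.2). STEAP1B and CR381670.2 were named only after their values were seen. The NF-kB list was called in this class (camera adjusted p = 0.00112; adjusted p = 0.340 with an estimated correlation), with IL33 at 0.91 ± 0.33, and it was the only list that fry called as moving one way. In pericytes or smooth muscle cells (5 pairs) HDAC9 (chromosome 7, 18086949 to 19002416) was lower at -1.11 ± 0.17 and MAMDC2 at -1.09 ± 0.22. RUNX1 (1.45 ± 0.28), SDC2 (0.88 ± 0.18) and VGLL3 (1.16 ± 0.24) were higher, and none of the 5 passed (edgeR adjusted p = 0.836 each). Blood endothelial markers were called lower there, 7 of 7 (median -0.94; camera adjusted p = 0.000731; adjusted p = 0.674 with an estimated correlation), a call that ended without pair 2 (camera adjusted p = 0.102), with doublets kept (0.946) and with automatic doublet calls (0.592). Of 8706 genes edgeR called 0, with 491 at an unadjusted p under 0.05, and DESeq2 called ADAMTS9 higher and HDAC9 lower. Without pair 5 edgeR called 1 gene, CDH12, named after its value was seen.

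In myeloid cells camera with the preset correlation called the heat shock, interferon and cholesterol synthesis lists higher. None was called with an estimated correlation (adjusted p = 0.330, adjusted p = 0.395 and adjusted p = 0.330), and 3, 3 and 2 genes passed adjusted over the list alone, 0 over all genes tested. HSPA5 was higher by 1.51 ± 0.30 (log2, SE, n = 6 pairs) and IFI44, an interferon-induced gene, by 0.70 ± 0.15. STARD4, a cholesterol carrier, was higher by 1.30 ± 0.29, and all 3 were higher in 6 of 6 pairs. CD207, the Langerhans cell marker, was lower at -1.13 ± 0.29 in 6 of 6 pairs and CD163, a macrophage marker, higher by 0.93 ± 0.23 in 5 of 6, the 2 markers passing adjusted over the list alone. The cluster with CD207 held 1.09% of control and 0.564% of irradiated nuclei, and the one led by CD163 1.99% and 2.32%. Both changes may therefore reflect the makeup of the class. MDM2 was higher by 0.96 ± 0.25 in 5 of 6 pairs. APP (1.21 ± 0.15; chromosome 21, 25880550 to 26171128), CEMIP2 (0.93 ± 0.13), IL7 (1.14 ± 0.17), PROS1 (1.07 ± 0.17) and IL1RL2 (-1.03 ± 0.17) had the smallest p, each the same way in 6 of 6 pairs.

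None of these myeloid genes passed in edgeR (adjusted p from 0.152 to 0.178 for the 5), which called 0 of 11541 with 1421 at an unadjusted p under 0.05, against 69 higher and 65 lower by DESeq2. Camera called the heat shock list at an adjusted p = 1.05e-07 (adjusted p = 0.330 with an estimated correlation) and the interferon list at 7.38e-06 (adjusted p = 0.395 with an estimated correlation). It called the cholesterol list at 0.000397 (adjusted p = 0.330 with an estimated correlation). T or NK cells (5 pairs) had P2RY8 (0.74 ± 0.14), CALN1 (-1.88 ± 0.36; chromosome 7, 71779491 to 72447151), GLIS3 (2.09 ± 0.40), IL34 (-1.497 ± 0.29) and RASA3 (0.74 ± 0.15) at the smallest p. None passed (edgeR adjusted p from 0.591 to 0.613). In that class edgeR called 0 of 8790 genes and DESeq2 0, with 438 at an unadjusted p under 0.05, and without pair 2 edgeR called 1, ANK3, named after its value was seen. Keratinocyte genes of the epidermal differentiation list were lower there (camera adjusted p = 1.03e-10; adjusted p = 0.371 with an estimated correlation), KRT2 at -1.66 ± 0.42 at 66.0% of its level over all nuclei. The call ended with doublets kept (camera adjusted p = 0.0642) or with automatic doublet calls (0.0832). Mast cells (5 pairs) had HDC, which makes histamine, higher by 0.80 ± 0.21 in 5 of 5 pairs. Mast cell markers, HDC among them, were called higher, 8 of 8 (median 0.32; camera adjusted p = 0.000543; adjusted p = 0.467 with an estimated correlation), a call that ended with doublets kept (camera adjusted p = 0.314) and with automatic doublet calls (0.691). Melanocytic markers were called lower in mast cells, 10 of 10 (median -1.07; camera adjusted p = 0.00173; adjusted p = 0.467 with an estimated correlation), which ended without pair 5 (camera adjusted p = 0.134) and with automatic doublet calls (0.0591). MACROD2 (-1.20 ± 0.22; chromosome 20, 13995369 to 16053197), BATF (1.27 ± 0.25), ADAMTS3 (1.48 ± 0.30), ERG (0.83 ± 0.17) and CTSG (1.25 ± 0.26) had the smallest p, and none passed (edgeR adjusted p from 0.555 to 0.556). There edgeR called 0 of 5276 and DESeq2 0, with 300 at an unadjusted p under 0.05. Sweat gland cells (6 pairs) had LTF, the iron binder lactoferrin (chromosome 3, 46435645 to 46485234), higher by 3.72 ± 0.47 in 6 of 6 pairs (edgeR adjusted p = 0.117). It was followed by HSD17B2 (1.80 ± 0.33), ELF3 (0.88 ± 0.17), SLC26A4 (1.79 ± 0.34) and FAM20C (1.54 ± 0.30; edgeR adjusted p from 0.806 to 0.861). None passed among 13511 genes, with 307 at an unadjusted p under 0.05, and DESeq2 called LTF alone. Suprabasal keratinocyte markers were called lower in sweat gland cells, 5 of 5 (median -0.90; camera adjusted p = 0.00328; adjusted p = 0.520 with an estimated correlation). That call ended without pair 4 or 6, with doublets kept, with automatic doublet calls and with a minimum of 50 nuclei (camera adjusted p from 0.0770 to 0.965). In irradiated sweat gland cells these markers stood at a median of 10.5% of their level over all nuclei, so free RNA could account for it.

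**Figure D3:**
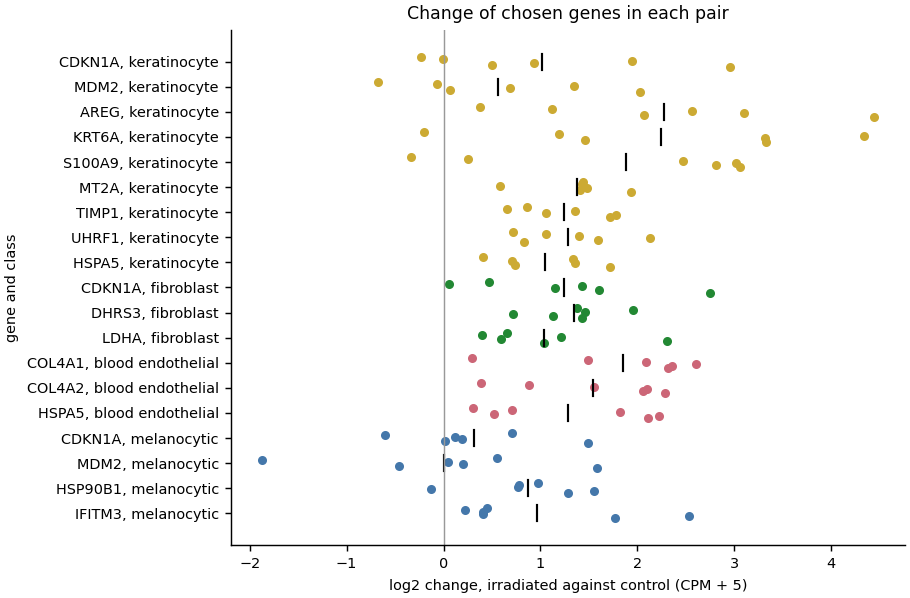
Change of chosen genes in each pair (horizontal axis, log2 of irradiated over control CPM with 5 added), by gene and class (vertical axis). Points are the 6 pairs, coloured by class, and black bars their means; COL4A1 and DHRS3 lie above 0 in all 6 pairs. CPM here is per library total, without the TMM scaling behind the counts of pairs in the text, so CDKN1A in keratinocytes lies above 0 in 4 of 6 pairs (5 with TMM) and MDM2 in melanocytic cells in 4 of 6 (3 with TMM).

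Camera with the preset correlation called ribosomal protein mRNAs higher in 11 of 13 class tests. The 13 tests are not independent, since all nuclei hold every class, keratinocytes hold both layers, and the pairs are shared. Of these calls 0 remained once the correlation was estimated (adjusted p = 0.434 to adjusted p = 0.942 with an estimated correlation), and 5 of them ended in at least 1 of the other settings too. They were not called in suprabasal keratinocytes (median 0.07, camera adjusted p = 0.0942) or in sweat gland, where 25 of 26 had a negative change (median -0.23, camera adjusted p = 0.926). Neither outcome was stable: a call appeared in 7 other settings in suprabasal keratinocytes and in 6 in sweat gland. In sweat gland the median of the list genes was higher in 4 of 6 pairs. The median was highest in myeloid cells (0.84, in 3 of 6 pairs; adjusted p = 1.05e-13, and adjusted p = 0.434 with an estimated correlation). In pericytes it was 0.75 (in 5 of 5 pairs; adjusted p = 1.01e-21, and camera adjusted p = 0.452 with an estimated correlation), where 18 of 26 passed adjusted over the list alone and 0 over all genes tested. RPLP0, a protein of the ribosome's stalk, was higher by 0.57 ± 0.14 over all nuclei in 6 of 6 pairs (SE). Heat shock and unfolded protein genes were called in 11 of 13 as well. None of the 11 remained once the correlation was estimated (adjusted p = 0.330 to adjusted p = 0.992 with an estimated correlation), and 4 of them ended in at least 1 of the other settings too. Over all classes camera made 115 calls at the preset correlation, 89 higher and 26 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.330. Fry called 1 list as moving one way and 42 as changing in either direction.

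Keratinocytes and melanocytic cells were compared for a difference in response within the same pairs. ROBO2, a guidance receptor, stood at -0.71 in keratinocytes and 1.13 in melanocytic cells, a difference of -1.88 ± 0.23 (log2, SE, n = 6 pairs). ITGA6, the integrin of basal cells, stood at 0.70 and -0.51, a difference of 1.25 ± 0.17. The change after irradiation was more positive in keratinocytes for NRP2 (a difference of 1.44 ± 0.24), RGS20 (1.79 ± 0.30) and SLC4A7 (1.30 ± 0.22). Each of the 5 genes differed the same way in 6 of 6 pairs. None passed (edgeR adjusted p from 0.252 to 0.535): of 17680 genes edgeR called 0, with 1228 at an unadjusted p under 0.05, and DESeq2 called 11 higher and 4 lower. Without pair 2, edgeR called ROBO2 alone. The makeup of both classes differed between the groups. Basal cluster 6 held 1.99% of control and 6.91% of irradiated nuclei (higher in 5 of 6 pairs). Melanocytic cluster 1, with RGS20 among its leading genes, held 10.3% and 6.87% (higher in 3 of 6 pairs). Differences such as those of ITGA6 and RGS20 may therefore reflect makeup, which was not tested. The S phase list differed by 0.60 ± 0.39 (SD, n = 6 pairs), from 0.52 in keratinocytes to -0.08 in melanocytic cells, in 6 of 6 pairs. The exact p was the smallest that 6 pairs allow (0.03125), which over 39 lists gave an adjusted p of 0.886 by the exact test.

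Other lists fixed beforehand were not called by camera in any class. Median changes ran from -0.16 to 0.07 for nucleotide excision repair over 13 classes, from -0.12 to 0.29 for G2 and M phase over 8, and from -0.28 to 0.29 for basal adhesion over 13. They ran from -0.06 to 0.20 for apoptosis over 13 and from -0.52 to 0.02 for collagen and dermal matrix over 12. The range was from -0.18 to -0.14 for T cell activation over 2 classes, from -0.22 to 0.25 for retinoid and vitamin D genes over 10 and from -0.13 to 0.03 for epigenetic regulators over 13. Medians near 0 can hide changes in both directions: fry called apoptosis as changing in either direction in 5 classes, retinoid and vitamin D genes and epigenetic regulators in 2 each, and basal adhesion in 1.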

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

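The tests of explanations in this part, with their gene sets and comparisons, were chosen only after the results were seen.

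Dixon's gap rule was run on 68 groups of 6 values, where chance alone marks about 1 in 20 groups, or 3.4 here, and it marked 8. In control libraries the highest share of T or NK cells was 11.45% (next 4.819%) and the highest share of adipocytes 8.893% (next 2.879%). In irradiated libraries the highest share of sweat gland cells was 31.68% (next 12.2%), the highest share of adipocytes 4.359% (next 0.8577%), and the lowest share of keratinocytes 5.598% (next 17.65%). The highest median in irradiated libraries was 6317 UMIs per nucleus (next 5280). In melanocytic cells S100A8 reached a log2 CPM of 2.244 in 1 control library (next 0.6393), and FST reached 5.099 in 1 irradiated library (next 2.325). Of the 8 marked values 5 lay in libraries of pair 2.

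Camera with the preset correlation called ribosomal protein mRNAs higher in 8 classes outside keratinocytes but not in sweat gland (median -0.23). The sweat gland outcome was unstable, with the median higher in 4 of 6 pairs and a call in 6 other settings. With an estimated correlation 0 of the 8 calls remained (adjusted p = 0.434 to adjusted p = 0.942 with an estimated correlation). Over those 8, chosen by the call, the mean was 0.45 ± 0.88 (log2, SD, n = 6 pairs), positive in 4 of 6 pairs (exact sign-flip p = 0.281). Free RNA from other cells could raise them. The percent of the keratinocyte marker level that reached these classes moved by only 0.04, and the gap of 0.41 exceeded its standard error of 0.36, the limit set beforehand against this cause. That limit was too lenient, since the gap varied between pairs with an SD of 0.87 and the ribosomal change itself cannot be told from 0. The markers also follow keratinocyte RNA alone, so free RNA stays open. For gene length and expression level, fewer than 5% of 1000 random lists matched on both reached the median change in 8 of these 8 classes. The matched lists had medians from -0.03 in blood endothelium to 0.23 in myeloid cells, against 0.14 and 0.80 for the ribosomal list. Ribosomal protein genes moved together (estimated correlation up to 0.967), which random lists need not, so these draws cannot exclude length and level. A biological cause remains open and untested.

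Wound keratin and S100 mRNAs were also counted outside keratinocytes, at 2.02% (lymphatic endothelium) to 15.9% (myeloid cells) of their keratinocyte level in irradiated libraries. If free RNA from keratinocytes carried them, they should stand there at about the percent of core keratins, with a log2 ratio within 1 of 0. Over 8 classes the ratio was -0.61 ± 0.24 (SE, n = 6 pairs), within that limit. The limit is wide, however, and the ratio lay below 0 by more than its SE. The means of lymphatic endothelium (-1.21 ± 1.26, SD) and pericytes fell outside it. Free RNA from keratinocytes thus stays possible, but the ratio cannot show it. Single classes ran from -1.39 ± 1.99 (SD, n = 5 pairs; pericytes) to 0.68 ± 1.14 (SD, n = 6 pairs; myeloid cells). In myeloid cells the wound genes stood higher than core keratins (15.9% ± 17.3 against 8.27% ± 6.26, SD), so expression by those cells themselves is not excluded. In fibroblasts the ratio was -0.40 ± 0.31 (SD, n = 6 pairs), within the limit, so the call of the wound list there may say little about fibroblasts themselves.

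The pairs differed in how much of the change they shared. The mean correlation of a pair's changes with those of the other pairs, over keratinocytes, fibroblasts and blood endothelium, was 0.02 and -0.05 in pairs 1 and 2 and from 0.39 to 0.55 in the other pairs. Whether labels were exchanged within a pair cannot be told: exchanging 1 pair raised the count of genes at unadjusted p under 0.05 in each of the 3 classes, but it was not the same pair, and 0 pairs did so in all 3. Too few nuclei do not explain it, since the pair with the fewest nuclei correlated at 0.43. A lower biological response in pairs 1 and 2 is a hypothesis that was not tested, and so is the unusual makeup of pair 2, where most of the marked values above lay.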

How the results depend on the processing

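The automatic doublet calls, the fit without the cluster that 1 library fills and the limit on free RNA are tests chosen only after the results were seen. The count of genes by edgeR was 0 in every class, and DESeq2 called 316 over all nuclei, 543 in keratinocytes, 63 in melanocytic cells, 539 in fibroblasts, 261 in blood endothelium, 134 in myeloid cells, 2 in pericytes (ADAMTS9 and HDAC9), 782 in the other classes and 15 for the difference of response. With no low-count filter edgeR called 15 genes in melanocytic cells, 8 in fibroblasts, 327 in blood endothelium, 57 in T or NK cells, 602 in myeloid cells, 78 in pericytes, 1819 in the other classes and 1 for the difference (ROBO2). With doublets kept it called 1 gene in melanocytic cells (AC011586.1), 1 in pericytes (RUNX1) and 2 for the difference (ROBO2 and PLXNA4). Thinned to the smallest library it called 10 genes in fibroblasts, 1 in the other classes (IGFBP5, lymphatic endothelium) and 1 for the difference (TENM2), and camera's 115 list calls became 67. Of the 115, 27 could not be tested after thinning for too few measured genes, 33 ended and 55 stayed, and 12 calls were new. ROBO2 was the 1 gene called for the difference at Leiden resolution 2 and with a minimum of 50 nuclei. Genes named here were chosen after their values were seen. With an estimated correlation 0 of the list calls remained. The causes were not tested.

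Leaving out each pair in turn gave 0 to 23 genes in keratinocytes (23 without pair 1), 0 to 3 in fibroblasts (2 without pair 1, 3 without pair 2, 1 without pair 4), 0 to 208 in blood endothelium (33 without pair 1, 208 without pair 2), 0 to 1 in T or NK cells (ANK3, without pair 2), 0 to 1 in pericytes (CDH12, without pair 5), 0 to 2891 in the other classes (2891 without pair 1, 3 without pair 2) and 0 to 1 for the difference (ROBO2, without pair 2). It gave 0 in all nuclei, melanocytic cells and myeloid cells, 0 for shares and quality, and 105 to 138 list calls. Without the volunteer block, which ignores the pairing, edgeR called 0 genes in every class, 0 shares passed, and 31 list calls ended, with no other call lost. Of 1873 checks of list calls 1486 were the same and 383 weaker, and thinning ended 33, automatic doublet calls 27 and keeping doublets 23. For single genes, 1128 checks covered 65 results, not every gene named here, and all kept their direction. Genes named for the smallest p often had the same sign in every pair, so leaving out a pair could hardly turn them.

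Some values turned direction when a pair was left out. The median of the list (pigmentation, all nuclei) ran from -0.4517 (without pair 1) to 0.0847 (without pair 2) and that of (ribosomal protein, blood endothelial) from -0.1996 (without pair 5) to 0.3807 (without pair 6). For the list (antigen presentation class I, melanocytic) the direction of camera's test turned without pair 5, while the median stayed above 0, from 0.0506 (without pair 5) to 0.4167 (without pair 4). In T or NK cells the ribosomal protein list came to -0.1083 with a minimum of 10 nuclei. The log2 ratio of median UMIs ran from -0.1536 (without pair 3) to 0.1229 (without pair 5), with -0.0192 without pair 2, and that of median genes from -0.076 (without pair 3) to 0.0962 (without pair 6). On the logit scale the difference in the share of melanocytic cells ran from -0.4884 to 0.2078 (without pairs 6 and 2) and in the share of myeloid cells from -0.0018 to 0.1216 (without pairs 1 and 2). In the share of T or NK cells it ran from -0.3143 to 0.34 (without pairs 6 and 2), with -0.0318 without pair 3, and in the share of mast cells from -0.0758 to 0.4135 (without pairs 1 and 4). The share of keratinocytes came to 0.0176 with the centred log-ratio, and that of T or NK cells to -0.0016 with automatic doublet calls.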

Other observations

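The exchanges of labels and the other splits in this part are tests run only after the results were seen.

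In blood endothelium the change after irradiation was 2.04 ± 0.49 (log2, SE, n = 6 pairs) for ADAMTS4, in 6 of 6 pairs, and 1.79 ± 0.47 for ADAMTS9, in 5 of 6. Both are proteases that cut matrix proteoglycans. In lymphatic endothelium ADAMTS5 stood at 2.54 ± 0.62 in 6 of 6 pairs and ADAMTS9 at 2.19 ± 0.56 in 5 of 6. Limma camera called the list of matrix metalloproteinases and related enzymes in both (adjusted p = 0.0257 and 0.0256; adjusted p = 0.483 and adjusted p = 0.511 with an estimated correlation), with 4 genes higher in each class adjusted over the list alone and 0 over all genes tested. In lymphatic endothelium 1 gene of the list was lower adjusted over the list alone, and 4 of 9 had a negative change, as had 3 of 9 in blood endothelium. Both calls ended without pair 5 and without the volunteer block. The call in blood endothelium also ended with doublets kept (camera adjusted p = 0.0533), with thinned counts (0.0905) and without pair 2 (0.130). Among circadian genes PER1, a clock repressor, was lower in keratinocytes (-0.89 ± 0.28, 6 of 6 pairs). The list was called there (camera adjusted p = 0.0156; adjusted p = 0.849 with an estimated correlation), a call that ended without pair 2 and at Leiden resolution 2.

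Labels were exchanged within pairs in every way that parts each pair, 32 splits with 6 pairs, the real one included. The count of genes called by edgeR was 0 for the real labels, so all 32 splits were as large. The highest other count was 0 in all nuclei, keratinocytes, melanocytic cells, lymphatic endothelium and sweat gland. It was 18 in fibroblasts, 141 in blood endothelium, 3 in myeloid cells, 2 in suprabasal keratinocytes and 1 for the difference of response. A split that calls 141 genes where the real labels call 0 points to a structure of the samples. Its cause was not tested, and pairs that differ in their response to irradiation could give it. For gene lists, the real count, the splits as large and the highest other were 19, 22 and 29 in all nuclei, 13, 18 and 20 in keratinocytes, 9, 23 and 22 in melanocytic cells, 15, 9 and 19 in fibroblasts. They were 9, 13 and 20 in blood endothelium, 9, 16 and 17 in myeloid cells, 9, 18 and 17 in suprabasal keratinocytes, 7, 23 and 14 in lymphatic endothelium and 6, 19 and 19 in sweat gland. The number of list calls was therefore no larger than other splits gave.

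By DESeq2, 2 of 32 splits were as large as the real count in all nuclei (316, highest other 1320), keratinocytes (543, 1009), fibroblasts (539, 833) and blood endothelium (261, 629). Genes at unadjusted p under 0.05 numbered 1421 in myeloid cells, the largest of 32 splits (highest other 1157), and ranked second in all nuclei (2082, highest other 3772), keratinocytes (2502, 2992), melanocytic cells (1129, 1182), fibroblasts (2534, 2856), blood endothelium (1815, 2440) and lymphatic endothelium (920, 1041). As many or more were found in 4 of 32 splits in suprabasal keratinocytes (934, highest other 1639), in 3 of 32 for the difference of response (1228, 1739) and in 23 of 32 in sweat gland (307, 789). With 5 pairs the 16 splits are too few to judge. There the real gene count was 0 and the highest other 1 in T or NK cells, 20 in pericytes, 1788 in basal keratinocytes and 3 in mast cells, all 16 splits being as large. The real list counts were 3, 3, 9 and 4, the highest others 11, 10, 14 and 5, and the splits as large 14, 15, 8 and 6.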
